A study of Mus musculus with 123 samples.

How the data were processed

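Liver RNA of mice on 2 diets and 3 photoperiods was measured at 6 zeitgeber times, 4 h apart, in libraries that form 36 groups. Per the labels' protocols, RNA was purified with Trizol and RNeasy columns, and poly-A RNA was made into stranded TruSeq libraries and read as pairs on a NovaSeq instrument. Per the submitters' processing notes, STAR, featureCounts and Subread 1.6.2 were used with the mouse genome build mm10 (GRCm38). The notes do not say which options or annotation were used, and the normalization step is not given in the sources used here. The authors deposited 1 table of 15398 genes whose values are log2 CPM per library, as the values themselves show. The lowest value, -3.6124, was the same in every library and stands for 0.08176 CPM. Taking that floor as a prior count of 2.0 reads scaled to each library, the values minus the prior came out as whole reads, within 0.05 read, for 99.43% to 99.76% of the values of a library. The recovered reads gave the depth per library, 13.97 M to 39.09 M reads (M, mega) with a median of 24.06 M. Because of the prior, a log2 difference understates the change of genes near the floor.

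Each column was matched to its sample by the name that the labels give, and 0 columns were left without a sample. Groups were taken from the sample titles. Replicate numbers follow the order of deposit and only name samples, and the titles carry a library number that was used as a covariate in an alternative. Among 153 pairs of libraries of the same group, the lowest chi-square per degree of freedom over genes with at least 20 reads was 14.53 and the median 61.17, so that no pair differed by as little as sampling noise and none was counted as 1 sample. Gene identifiers were matched to GENCODE mouse release 21 on GRCm38, where 15379 of 15398 (99.88%) were found, and positions are 1-based. Of 1409 genes without a deposited symbol, 1395 took theirs from GENCODE, and 20 symbols occur more than once.

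Genes with at least 1 CPM in at least 3 libraries were kept, 14397 in all. Limma 3.58.1 in R 4.3.3 was fitted to the deposited log2 values with a trend of the variance on expression. Levels were compared in a model with 1 mean per group, over all libraries, with contrasts that weight groups equally: HFD vs LFD over all photoperiods and within each, Long vs Short, Long vs Equal and Short vs Equal light with both diets, Long vs Short within each diet, and the diet by photoperiod interaction. Rhythms were fitted as a cosine and a sine of 24 h per arm, with F tests for rhythm in each arm and for differences of both coefficients between photoperiods, diets and their interaction. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The planned count models were not run: the deposited table holds no counts, limma-trend was the fallback fixed for that case, and limma-voom was run on the recovered reads as the alternative closest to a count model.

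The clock shift between 2 arms was the mean circular difference in peak time over 15 clock genes. Its SE came from a jackknife within groups. Its p came from a two-sided permutation of the arm labels within time (100000 permutations) with Benjamini-Hochberg over the 7 shifts, and alternatives used 10000 permutations. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list moves on balance in a single direction or in either direction. The 30 lists cover the clock and its output, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and ketogenesis, lipid droplets and lipid uptake, bile acids, drug metabolism, gluconeogenesis and fasting, glycolysis, heat shock and temperature response, the unfolded protein response, the acute phase, the interferon response, the cell cycle, male-biased and female-biased liver genes, macrophages and Kupffer cells, lymphocytes, neutrophils, stellate cells and matrix, endothelial cells, cholangiocytes, adipocytes, pancreas acinar cells, blood, periportal and pericentral hepatocytes, the respiratory chain, the mitochondrial genome and ribosome biogenesis. Skeletal muscle was added after its genes were seen to vary between libraries. The lists, models, tests, gene naming rule and most alternatives were fixed before the data were examined.

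Named genes follow a rule: the 15 clock genes, the 8 largest increases and 8 largest decreases between diets among called genes with a mean log2 CPM of at least 2 and the same sign in all 3 photoperiods, up to 4 members of each list with the smallest p in the comparison described, the 5 genes with the largest smallest-arm amplitude, and up to 6 genes with the smallest p for each interaction and rhythm difference. Unnamed gene models were counted but not named, and some genes that the rule takes are not reported here. The scripts were tested on simulated data built from these libraries. For HFD vs LFD, 65.7%, 94% and 100% of genes changed by 0.25, 0.5 and 1 on the log2 scale were recovered, for Long vs Short light 58.2%, 91% and 100%, and for rhythm in LFD Long light 53% and 86% at amplitudes of 0.3 and 0.6, with 5 or 6 false calls. A clock shift of 3 h was recovered as 3.032 h (SD 0.245), and 0 of 20 runs without a shift gave a permutation p under 0.05. In these simulations noise was drawn independently for each gene, so variation that the genes of a library share was left out. The recovery rates, false calls and SD may therefore look better than they would for real libraries.

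The alternatives were RLE normalization, no filter on low values, pseudocounts of 0.1 and 1, leaving out each replicate number, library number as a covariate, a contrast of the cosine means, time as a factor, an added 12 h cosine, limma-voom, 8 clock genes, the median over clock genes, and the other list tests. Chosen after seeing the data were limma-voom for levels, the pseudocount of 1, covariates for muscle and pancreas markers, and fits without the libraries rich in those markers, without the 2 libraries farthest from their groups, without 9 libraries whose clock genes read a time over 4 h from the label and without library numbers 49 to 64. Numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used besides R. Depth sets the counting error, and the floors and p-values here cover no error made before the libraries were read.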

Results

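RNA was sequenced from the liver of mice fed a high fat diet (HFD) or a low fat diet (LFD) under 3 photoperiods, which the labels call Equal light, Long light and Short light. Livers were collected at 6 zeitgeber times (ZT), at ZT0, 4, 8, 12, 16 and 20 h over 1 daily cycle. The design crosses both diets with the 3 photoperiods and the 6 times, which gives 36 groups, 21 of them with 3 libraries and 15 with 4. There were 61 HFD libraries and 62 LFD libraries. A diet and photoperiod together are called an arm here, and the 6 arms held 20 or 21 libraries each. The labels give neither the hours of light and dark in each photoperiod nor the event from which ZT0 was counted. They name no animals, so that the replicates are separate samples only by their labels, and the p-values measure the spread between these samples. Recovered depth ran from 13.97 M to 39.09 M reads (M, mega) per library with a median of 24.06 M. The mean per arm lay between 23.53 ± 4.42 M (SD, n = 21) in HFD Short light and 25.57 ± 5.2 M (SD, n = 21) in LFD Short light. At this depth 1 read was worth 0.0422 CPM (reads scaled to a common library total) on average.

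The first comparison asked how liver expression differed between the diets over all photoperiods and times. Among called genes with a mean log2 CPM of at least 2 and the same sign in all 3 photoperiods, Fabp5, a fatty acid binding protein, was the most reduced, 6.56-fold lower in HFD (log2 difference -2.71, SE 0.258), followed by Pnpla3, which encodes a lipid droplet protein, and Lepr, the leptin receptor, which were 3.55-fold and 3.53-fold lower. Adgrf1, Chrna4, the pseudogene Serpina4-ps1, Srgap3 and G6pdx, whose enzyme opens the pentose phosphate pathway, were 3.25-fold, 2.63-fold, 2.29-fold, 2.26-fold and 2.20-fold lower. Cyp4a14, a fatty acid omega-hydroxylase and a target of the receptor PPARα, was 3.11-fold higher in HFD (log2 difference 1.64, SE 0.372), and its relative Cyp4a10 was 2.11-fold higher. Adgrv1, Aatk, Tmem28 and Lcn2 were 2.57-fold, 2.29-fold, 2.19-fold and 2.09-fold higher. The major urinary protein genes Mup18 and Mup17 were 2.79-fold and 2.70-fold higher, but they belong to a family of near-identical copies that counting can split, so their values are uncertain. Over all genes, limma called 3676 of 14397 past an adjusted p of 0.05, 1859 higher and 1817 lower in HFD, and 251 of them differed by more than 1.5-fold. Fabp5, Lepr, Adgrf1, Srgap3 and G6pdx were lower, and Aatk and Tmem28 higher, in each of the 18 pairs of HFD and LFD groups matched for photoperiod and time. Cyp4a14 was higher in 14 of the 18 pairs. Without replicate 1 of every group the count was 2282, and Cyp4a14 had an adjusted p of 0.0552 and Chrna4 one of 0.0706.

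Level and position are given for the genes that led this comparison, on build GRCm38. Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607, plus strand) stood at a log2 CPM of 3.99 ± 1.62 (SD, n = 61) in HFD and 6.75 ± 1.33 (SD, n = 62) in LFD, with an adjusted p of 3.97e-14. Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, plus strand) stood at 2.15 ± 0.67 in HFD and 3.97 ± 1.04 in LFD, with an adjusted p of 3.81e-18. Pnpla3 (ENSMUSG00000041653, chromosome 15, 84167837 to 84187236, plus strand) stood at 2.25 ± 1.86 and 4.16 ± 1.90 log2 CPM, with an adjusted p of 9.62e-07. Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142, minus strand) stood at 5.92 ± 2.20 in HFD and 4.23 ± 2.23 in LFD, with an adjusted p of 0.000393. Aatk (ENSMUSG00000025375, chromosome 11, 120007313 to 120047167, minus strand) stood at 3.57 ± 0.75 and 2.38 ± 0.60 log2 CPM. Adgrv1 (ENSMUSG00000069170, chromosome 13, 81095068 to 81633154, minus strand) stood at 3.21 ± 0.80 and 1.84 ± 0.62 log2 CPM. The SDs span all times and photoperiods, so they hold the daily rhythm as well as the spread between replicates. All 6 are annotated as protein-coding genes, and each value covers reads over the whole gene.

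**Figure D1:**
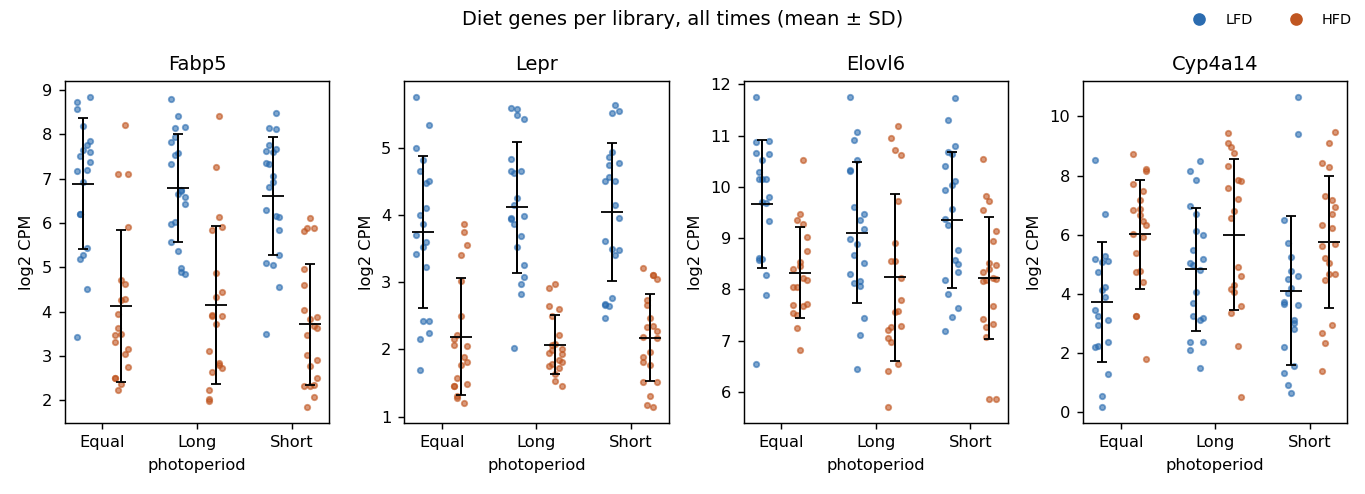
Log2 CPM of Fabp5, Lepr, Elovl6 and Cyp4a14 by diet and photoperiod, with each point a library of any time and the bar and whiskers the mean and SD of the arm. Fabp5 lies lower in HFD, with a mean of 3.99 over the 61 HFD libraries against 6.75 over the 62 LFD libraries.

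Genes of lipid metabolism moved in opposite directions by function. Fatty acid oxidation and ketogenesis genes rose in HFD, 24 of the 26 measured, among them Cpt2 of the mitochondrial carnitine shuttle (log2 difference 0.31, adjusted p 2.19e-11), the dehydrogenase Acadm (0.35, adjusted p 3.94e-09), the carnitine carrier Slc25a20 (0.28) and Etfdh (0.23), which passes electrons from fatty acid oxidation to the respiratory chain. Of 16 lipid droplet and lipid uptake genes 12 rose and 1 fell, with rises of Fitm1 (0.73), the lipogenic regulator Pparg (0.80) and the fatty acid receptor Cd36 (0.72, adjusted p 2.01e-06). Mogat1 rose by 0.99 from a level near the lower end of detection. Fatty acid synthesis genes fell, 13 of 20, with Elovl6 at -1.06 (SE 0.198, adjusted p 1.70e-05, 2.09-fold lower), Me1 at -0.91 and Acaca, the first committed enzyme of the pathway, at -0.76 on the log2 scale. Cholesterol synthesis genes fell as well, 14 of 24, with Pmvk at -0.56, Tm7sf2 at -0.37 and the sterol carrier Stard4 at -0.34. Adjusted over the list alone, the counts were 25 higher for oxidation, 13 higher and 1 lower for lipid droplets, 13 lower for fatty acid synthesis and 14 lower for cholesterol synthesis. By camera with a preset correlation of 0.01 between genes, the adjusted p was 3.89e-18 for oxidation, 1.32e-06 for lipid droplets, 2.13e-06 for fatty acid synthesis and 3.24e-05 for cholesterol synthesis. These list calls were lost when the correlation was estimated from the data, with adjusted p = 0.0914 with an estimated correlation for oxidation, adjusted p = 0.256 with an estimated correlation for lipid droplets and adjusted p = 0.621 with an estimated correlation for both synthesis lists. Without replicate 1, Pmvk and Tm7sf2 had adjusted p-values of 0.0699 and 0.101.

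**Figure D2:**
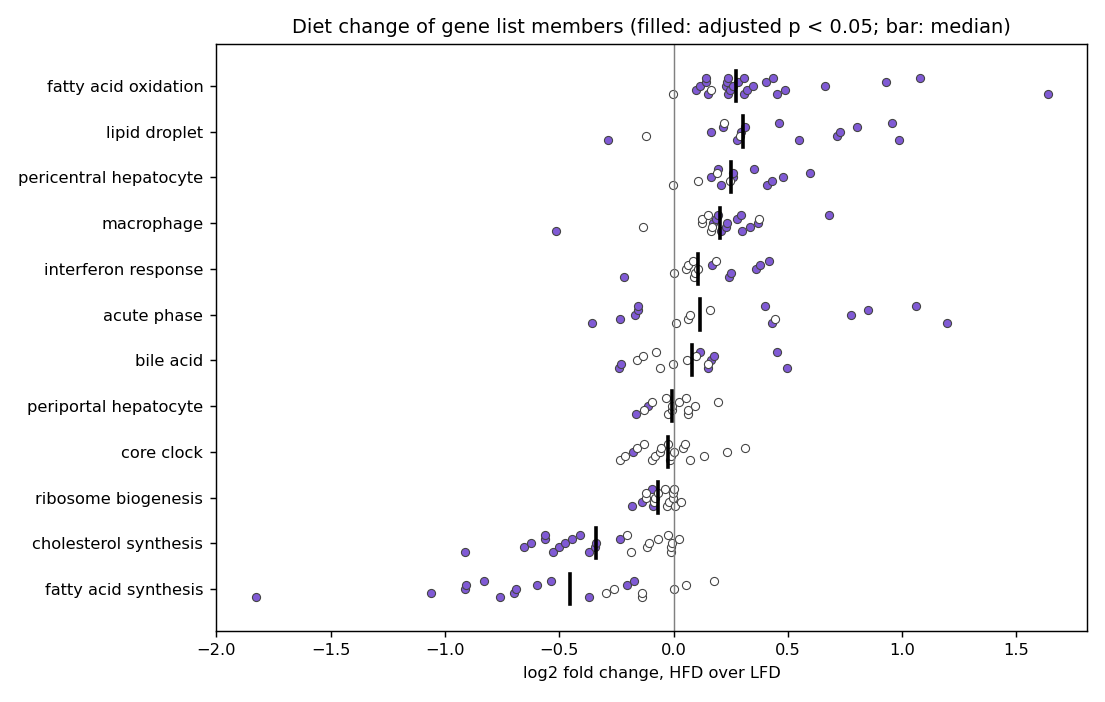
Log2 difference between HFD and LFD of each measured gene of 12 preset lists, with each point a gene, filled where its adjusted p was under 0.05, and a bar at the list median. Of the 26 fatty acid oxidation and ketogenesis genes, 24 were higher in HFD, and of the 20 fatty acid synthesis genes, 13 were lower.

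Markers of the pericentral zone of the liver lobule, the zone around the central vein, rose in HFD, 10 of 14 measured (12 adjusted over the list alone), with Lect2 at 0.43 (adjusted p 1.02e-13), Oat at 0.60 (adjusted p 1.67e-11) and Lgr5 at 0.48 on the log2 scale. This was the only list tested between diets that kept its call with an estimated correlation (camera adjusted p 1.64e-09, and 0.0141 with an estimated correlation). Among 19 drug metabolism genes 6 rose and 2 fell (7 and 4 adjusted over the list alone). The xenobiotic receptor Nr1i3 rose by 0.78 (adjusted p 1.08e-08). Cyp2b9, also a member of the female-biased list, was 11.3-fold higher (log2 difference 3.49, SE 0.462, adjusted p 4.34e-09), at 3.13 ± 2.68 log2 CPM (SD, n = 61) in HFD against -0.39 ± 2.0 (SD, n = 62) in LFD. Cyp2b9 lies on chromosome 7, 26173411 to 26210661. Cyp2b13, close to the floor of the table, rose by 1.55 and Cyp2a5 by 0.50. These Cyp2 genes have close paralogs, so reads can be split between copies.

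Markers of macrophages and Kupffer cells, the resident macrophages of the liver, rose in HFD in 12 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone), with Trem2 at 0.68, Cd5l at 0.30 and Clec4f at 0.21, against Cd9 at -0.52 (adjusted p 2.28e-07). Interferon response genes rose in 6 of 15 cases and fell in 1 (7 and 1 adjusted over the list alone), with Rsad2 at 0.38, Ifit1 at 0.36 and Ifit3 at 0.25, against Bst2 at -0.22. Stellate cell and matrix genes rose in 3 of 13 cases (4 adjusted over the list alone), Colec11 at 0.17, Ecm1 at 0.15 and Reln at 0.145. Ribosome biogenesis genes fell in 4 of 17 cases (4 adjusted over the list alone), with Npm1 at -0.18, Ncl at -0.10, Fbl at -0.09 and Nop56 at -0.14. Camera gave adjusted p-values of 0.000264 for macrophages, 0.00721 for interferon, 0.0377 for stellate cells, 0.04 for ribosome biogenesis and 0.04 for drug metabolism. All 5 camera calls were lost, with adjusted p = 0.621 with an estimated correlation in each. Fry kept the 5 lists in a single direction (adjusted p from 0.00521 to 0.0206) but not in either direction (from 0.14 to 0.961). Ecm1 lost its call without replicate 3 (adjusted p 0.393), Fbl without replicate 1 (0.318) or 2 (0.142) and Nop56 without any 1 of the 4 replicates (0.0666 to 0.126).

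Digestive enzyme genes of pancreas acinar cells were lower in HFD livers, 11 of 12 measured (11 adjusted over the list alone), with log2 differences of -1.96 for Pnlip (SE 0.573), -1.84 for Cpa1, -1.76 for Cel and -1.56 for Cela2a (SE 0.452), and adjusted p-values from 0.00616 to 0.00953 for these 4. All 4 lost the call in the planned fits without replicate 1 (adjusted p from 0.177 to 0.233) and without replicate 3 (from 0.0807 to 0.125). The mean level of the 12 markers was -1.28 ± 2.25 log2 CPM (SD, n = 61) in HFD and 0.16 ± 3.09 (SD, n = 62) in LFD. High levels were found in few libraries, of which 12 had a mean pancreas marker level above a log2 CPM of 4, 3 of them HFD and 9 LFD, and 14 had such a level of skeletal muscle markers. Camera gave an adjusted p of 0.000438, and the call was lost, with adjusted p = 0.621 with an estimated correlation. Fry kept it in a single direction (adjusted p 0.0193) but not in either direction (0.778). Without the 24 libraries rich in either marker, an alternative chosen after seeing the data, 0 of the 12 passed in limma as lower (4 at an unadjusted p under 0.05), with a median log2 difference of -0.79 in place of -1.60. Limma-voom called 0 of the 12 lower over all libraries, although its log2 differences for Pnlip (-2.69, adjusted p 0.156) and Cela2a (-1.77, adjusted p 0.123) were larger than those of limma.

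Within single photoperiods the diet was compared over the 6 times of each. HFD and LFD differed in 986 genes in Equal light (504 higher, 482 lower), 699 in Long light (463 higher, 236 lower) and 990 in Short light (538 higher, 452 lower). Of the 3676 genes called over all photoperiods, 3589 (97.6%) had the same sign in all 3, a share raised by their selection on the pooled call. Across all 14397 genes the diet differences correlated between photoperiods with Pearson's r of 0.649 for Equal and Long light, 0.694 for Equal and Short light and 0.644 for Long and Short light, and genes are not independent replicates. The diet by photoperiod interaction, which tests the difference between these effects directly, gave 0 genes past the threshold in limma and 0 in limma-voom, with 483 genes at an unadjusted p under 0.05 in limma. Without the libraries rich in muscle or pancreas markers, the Long light count was 189. Without replicate 1 of every group the counts were 194 in Equal light, 172 in Long light and 120 in Short light.

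The next comparison asked whether average expression over the cycle differed between photoperiods. Periportal hepatocyte markers, of the zone around the portal vein, were on balance lower in Long light than in Short light, with a median log2 difference of -0.088 over 14 genes. Ass1 of the urea cycle (-0.22, SE 0.061) and the glutaminase Gls2 (-0.16, SE 0.043) were the 2 members past the threshold adjusted over the list alone, and both had an adjusted p of 1 over all genes. Camera gave an adjusted p of 1.54e-07, and of 0.00784 with an estimated correlation, and fry gave 0.0433. Genes of the mitochondrial genome (adjusted p 0.000221), gluconeogenesis and the fasting response (0.000252), the respiratory chain (0.000598) and pancreas acinar cells (0.0167) were also lower and blood genes higher (0.000252) by camera. These calls were lost, with adjusted p = 0.365 with an estimated correlation for the mitochondrial genome, gluconeogenesis and blood and adjusted p = 0.841 with an estimated correlation for the respiratory chain and pancreas. Skeletal muscle markers had a median difference of 0.781 between Long and Short light (camera p 3.47e-06, and 0.183 with an estimated correlation), and 10 Long light and 6 Short light libraries were rich in muscle or pancreas markers. No single gene passed between Long and Short light: limma gave 0 genes with both diets together (402 at an unadjusted p under 0.05), 0 within LFD (792) and 0 within HFD (283), and limma-voom gave 0 in each. The half-width of the 95% interval of this difference had a median of 0.109 on the log2 scale and was under 0.5 for 98.5% of genes.

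Against Equal light 5 genes passed. They lie outside the rule for named genes and are named because the count was small, after their values were seen. G0s2, an inhibitor of triglyceride lipolysis, was higher in Long than in Equal light (log2 difference 0.78, SE 0.156, adjusted p 0.0174). Amn1 (-0.40, adjusted p 0.0174), Hnrnph2 (-0.135, adjusted p 0.0351) and the mitochondrial ornithine carrier Slc25a15 (-0.16, adjusted p 0.0488) were lower in Long light. C2cd5 was lower in Short than in Equal light (-0.23, SE 0.04, adjusted p 0.00272). In all, limma and limma-voom each called 4 genes between Long and Equal light and 1 between Short and Equal light. At an unadjusted p under 0.05 limma gave 2106 and 2385 genes. The 2 libraries farthest from their groups were both in Equal light, and without them the 4 genes of Long light had adjusted p-values from 0.0681 to 0.117. Without the libraries rich in muscle or pancreas markers, G0s2 had a log2 difference of 0.76 with an adjusted p of 0.198 and C2cd5 one of -0.19 with an adjusted p of 0.352, and all 5 lost the call without replicate 3 (0.597 for the 4 genes of Long light, 0.297 for C2cd5).

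Daily rhythms were then tested in each arm with a cosine of 24 h. Among genes rhythmic in every arm with a mean log2 CPM of at least 2, the clock output gene Dbp had the largest swing, with amplitudes from 3.08 to 3.71 on the log2 scale (mean to peak). Per3, Arntl (Bmal1), Nr1d1 and the deubiquitinase gene Usp2 came next, ranked by the smallest amplitude in any arm. Arntl (chromosome 7, 113207465 to 113314126) had amplitudes from 1.93 to 2.59 and Npas2, a paralog of Clock whose product pairs with that of Arntl, from 2.95 to 3.97. Hlf had the lowest amplitude of the 15 clock genes, 0.13 in HFD Equal light, and was rhythmic in 5 of the 6 arms. In LFD, limma called 3012 genes rhythmic in Equal light, 3395 in Long light and 3906 in Short light, and in HFD 2372, 3137 and 2034. Over the 6 arms 592 genes were rhythmic in all, 7417 in at least 1 and 6980 in none. Counts in separate arms do not test a difference between them, and that test follows with the rhythm differences. Without the libraries rich in muscle or pancreas markers the count was 1303 in LFD Equal light and 1874 in LFD Long light. With 1 replicate number left out of every group at a time, the counts ranged over 1051 to 3175, 1782 to 2991 and 1611 to 3798 in LFD Equal, Long and Short light and over 940 to 2246, 1114 to 2532 and 835 to 1628 in HFD, and Hlf was rhythmic in 2 arms without replicate 1.

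**Figure D3:**
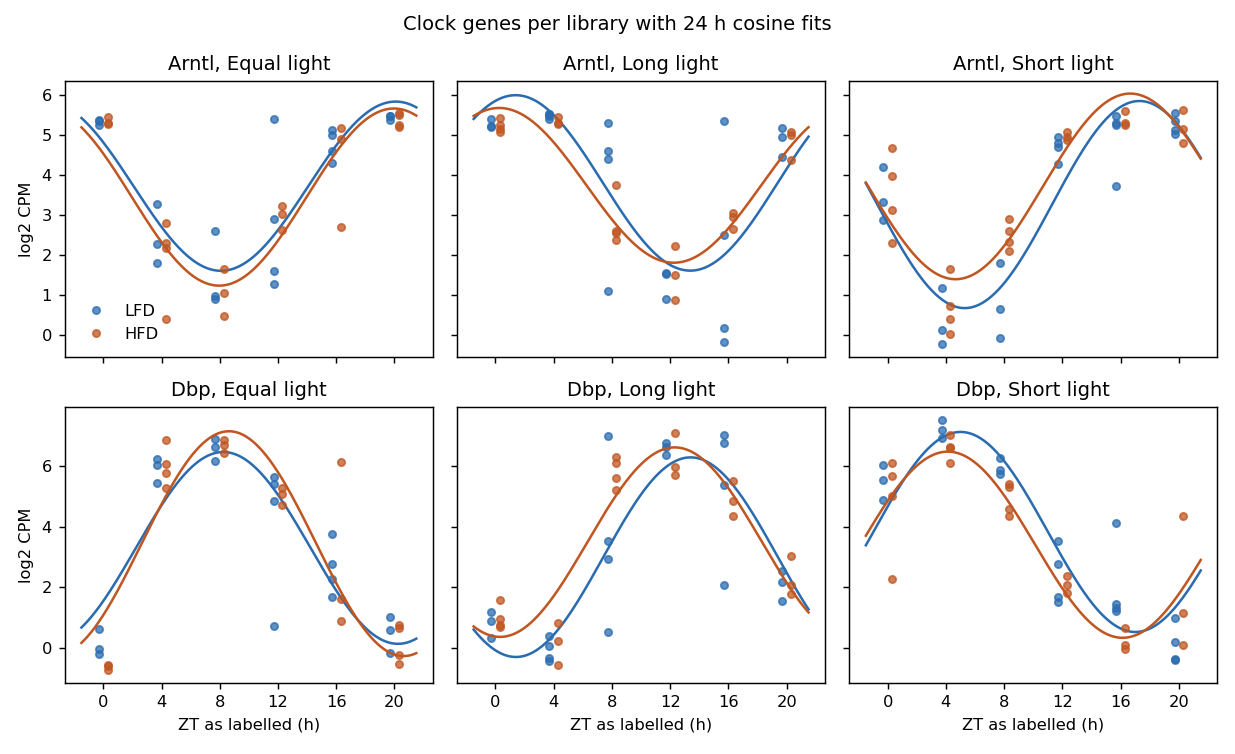
Log2 CPM of Arntl and Dbp by zeitgeber time in h for each diet and photoperiod, with points for libraries and the fitted 24 h cosine as a line. In LFD the fitted peak of Dbp lies at ZT 8.24 in Equal light, 13.4 in Long light and 5.01 in Short light.

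Clock genes peaked later in Long light and earlier in Short light than in Equal light on either diet. In LFD, Dbp (chromosome 7, 45705088 to 45710203) peaked at ZT 8.24 ± 0.55 h (SE) in Equal light, 13.4 ± 0.55 h in Long light and 5.01 ± 0.46 h in Short light. Arntl, which peaks opposite to Dbp, peaked at ZT 20.08, 1.38 and 17.29 in the same order. The repressor gene Nr1d1 peaked at ZT 6.01, 10.43 and 2.04, and Per3 at ZT 10.08, 15.03 and 6.99. In HFD, Dbp peaked at ZT 8.63, 12.31 and 4.13 and Arntl at ZT 19.96, 0.25 and 16.66. Over the 15 clock genes, which include Arntl, Npas2, Clock, Cry1, Nr1d1, Per1, Per2, Per3, Dbp, Tef and Hlf, Long light was later than Equal light by 5.01 h in LFD (SE 0.52, 95% interval 3.98 to 6.04) and by 4.0 h in HFD (SE 0.41, 3.19 to 4.81), with all 15 genes later in each diet. The shift of Short from Equal light was -3.24 h in LFD (SE 0.38, -3.98 to -2.5) and -4.17 h in HFD (SE 0.38, -4.92 to -3.41), with all 15 genes earlier. Two-sided permutation tests within time gave adjusted p-values of 2.33e-05 for both Long light shifts and for the HFD Short light shift, and 0.000105 for the LFD Short light shift, and 1e-05 was the smallest unadjusted p that the 100000 permutations could give. Because the labels do not say what ZT0 marks in each photoperiod, these are shifts on the labelled time scale. They include 9 libraries whose clock genes read a time over 4 h from the label, which are described below.

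Between diets the clock differed by about 1 h or less. HFD was earlier than LFD in Short light, with a shift of -0.97 h (SE 0.32, 95% interval -1.58 to -0.35, permutation adjusted p 0.0201) and 14 of the 15 clock genes earlier. In Long light the shift was -1.05 h (SE 0.51, -2.04 to -0.06) with all 15 genes earlier, and it did not pass the permutation test (adjusted p 0.123). In Equal light it was -0.04 h (SE 0.44, -0.89 to 0.82, adjusted p 0.945), with 7 genes later and 8 earlier. The photoperiod shifts themselves did not pass a permutation test of their difference between diets, with -1.01 h for Long minus Equal light (p 0.218) and -0.93 h for Short minus Equal light (p 0.164), both at an adjusted p of 0.218. The Short light difference lost its call without replicate 1 (adjusted p 0.0805) or replicate 4 (0.0879) and with the median over genes in place of the mean (0.0553).

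**Figure D4:**
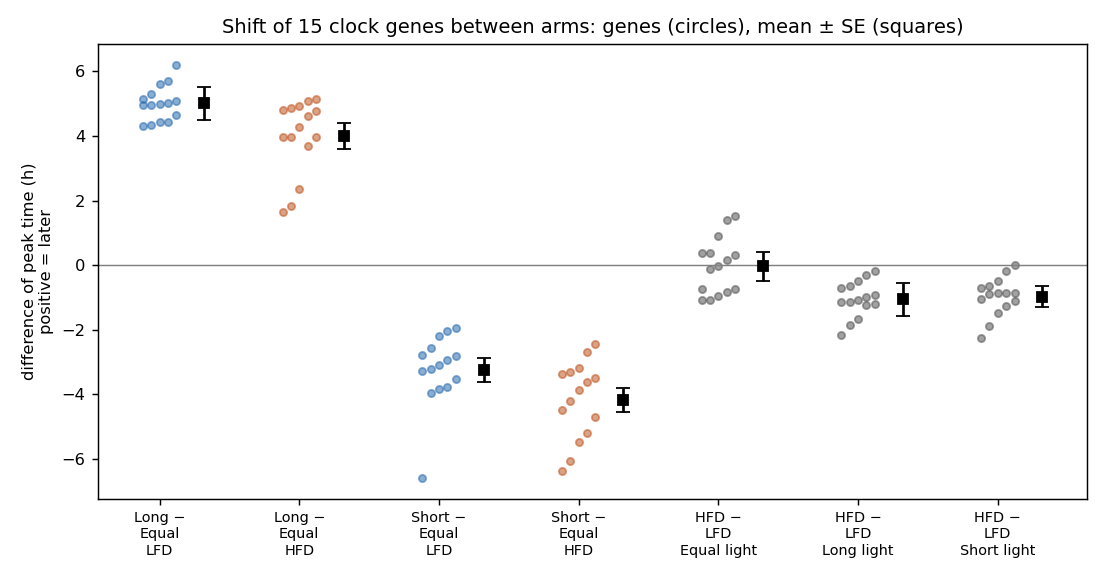
Shift of the peak of the 15 clock genes in h between arms, with circles for genes and squares for the mean with its SE. All 15 genes are later in Long than in Equal light on both diets, with means of 5.01 h in LFD and 4.0 h in HFD.

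Rhythms differed between photoperiods in many genes and between diets in 1. Between Long and Short light, genes with some of the smallest p-values were Clpx, a mitochondrial chaperone (chromosome 9, 65294260 to 65330658, adjusted p 6.19e-22), Tef (3.31e-21), Dbp (6.79e-21), Coq10b (6.79e-21) and the uridine phosphorylase gene Upp2 (1.16e-20). Long and Equal light differed in the rhythm of Clpx (4.15e-12) and Mreg (1.32e-10) among others, and Short and Equal light in Dbp (2.57e-07) and Tns2 (3.78e-07). The count was 7612 genes for Long and Short light, 3421 for Long and Equal light and 2349 for Short and Equal light. Slc25a48, a mitochondrial carrier gene (chromosome 13, 56438355 to 56474239), was the 1 gene whose rhythm differed between diets (adjusted p 0.0149), with an amplitude of 0.483 in HFD and 0.166 in LFD in Equal light. The diet by photoperiod term of the rhythm gave 0 genes in limma and 0 in limma-voom, with 758 at an unadjusted p under 0.05 in limma. With 1 replicate number left out at a time, the count ranged over 1376 to 3181 for Long and Equal light and over 818 to 2463 for Short and Equal light. In 9 libraries the clock genes read a time over 4 h from the label, 8 of them among the 16 libraries numbered 49 to 64, and without those 16 the counts between photoperiods were 8047, 4166 and 3277. Slc25a48 lost its call with a 12 h cosine added (adjusted p 0.0686), with time as a factor (0.329), without the marker-rich libraries (0.224) and without replicate 1 (1), 2 (0.0939) or 3 (0.89).

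By gene list, the rhythm differed between Long and Short light in all 14 heat shock and temperature response genes, in 18 of 19 clock and clock output genes, 15 of 17 ribosome biogenesis genes, 14 of 16 bile acid synthesis and transport genes, 14 of 16 respiratory chain genes and 12 of 14 periportal genes. Adjusted over the list alone, the counts were 14, 19, 15, 14, 15 and 13. The chaperone gene Hsp90aa1 peaked at ZT 18.19 in Equal light, 22.81 in Long light and 13.3 in Short light in LFD, and Hsph1 at ZT 16.92, 21.22 and 12.15. The bile salt export pump gene Abcb11 peaked at ZT 0.89, 5.29 and 20.94 in the same arms, and Asl of the urea cycle at ZT 19.22 in Long light and 10.67 in Short light. Few or no members differed among macrophage markers (2 of 20), pancreas acinar genes (0 of 12) and genes of the mitochondrial genome (0 of 7). Over all genes tested, 7612 of 14397 differed. The mean pancreas marker level was low in most libraries (median log2 CPM -2.03) and above 4 in 12. A rhythm of these genes would be hard to detect under that spread, so their count does not show that a rhythm was absent. For the pancreas and mitochondrial lists the count was also 0 in limma at an unadjusted p under 0.05, and 0 in limma-voom. Two-sided Fisher's exact tests of each list against all other genes gave adjusted p-values of 0.00119 for heat shock, clock, macrophages and pancreas, 0.0178 for ribosome biogenesis, 0.0193 for bile acids, the respiratory chain and the mitochondrial genome and 0.0497 for periportal genes. Genes of a list are not independent of each other, which makes these p-values too small.

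Each arm was then moved in time by its own clock shift, and the rhythm differences were tested again over the 14382 genes outside the 15 clock genes, a step chosen after seeing the data. As labelled, 7594 of these genes differed between Long and Short light, 3397 between Long and Equal light and 2332 between Short and Equal light. After the move, limma called 0 in each of the 3 comparisons, with 1641, 947 and 1307 at an unadjusted p under 0.05, and limma-voom called 0 in each. Each of these unadjusted counts exceeds the share of 0.05 that chance gives for independent genes, so differences beyond a common shift may remain. Genes outside the clock set that were rhythmic in both arms peaked a median of 8.06 h later in Long than in Short light in LFD (1931 genes, quartiles 6.95 to 9.15) and 8.02 h later in HFD (1375 genes, quartiles 7.17 to 8.82), against 8.24 h and 8.16 h for the clock genes. On simulated data with a rhythm added to LFD Long light alone, the rhythm difference test found 8% of genes at an amplitude of 0.3 and 44% at 0.6. The test averages both diets, so the difference it saw was smaller than these amplitudes. Differences shared by both diets were not simulated, and small differences could have been missed.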

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

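The comparisons of genes, rhythms and clock shifts were planned. Of the tests of explanations for them, those of muscle or pancreas RNA and of low depth in the libraries with a deviating clock, and those that leave libraries out for the pancreas markers, were set before their results were seen, and the others in this part were chosen after.

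In groups of 4 libraries, a library stood apart from the other 3 of its group by Dixon's test in 16 of 165 tests (11 measures in 15 groups), where chance gives about 1 in 20. Depth was 27.14 M reads in LFD Equal light ZT12 replicate 1, against 22.43 M to 23.14 M in the others. The mean skeletal muscle marker level in log2 CPM was -3.31 in HFD Short light ZT4 replicate 4 (others 2.22 to 3.23), 2.52 in LFD Long light ZT8 replicate 3 (-3.14 to -2.91) and 3.14 in LFD Short light ZT16 replicate 4 (-3.09 to -2.38). The mean pancreas marker level was 2.96 in HFD Short light ZT0 replicate 4 (-2.55 to -2.44) and 7.07 in LFD Long light ZT4 replicate 4 (-2.01 to -0.93). The time read from the clock genes lay 7.50 h after the label in LFD Equal light ZT12 replicate 4 (-1.0 to 0.0 h), where Dbp stood at 0.72 log2 CPM (4.85 to 5.64). In LFD Short light ZT16 replicate 4, Dbp stood at 4.11 (1.22 to 1.45) and Arntl at 3.72 (5.25 to 5.47), and in HFD Long light ZT8 replicate 2 Arntl stood at 3.74 (2.38 to 2.59). Fabp5 stood at 8.20 in HFD Equal light ZT4 replicate 3 (3.94 to 4.62), at 5.89 in HFD Short light ZT0 replicate 3 (2.32 to 2.91) and at 6.28 in LFD Short light ZT16 replicate 3 (7.62 to 7.76). Cyp4a14 stood at 6.96 in LFD Long light ZT16 replicate 4 (1.49 to 2.39) and Elovl6 at 7.33 in HFD Short light ZT0 replicate 3 (8.20 to 8.34).

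Effects differed between groups by their own tests in the rhythms of 7612 genes (Long vs Short light), 3421 (Long vs Equal), 2349 (Short vs Equal) and 1 (HFD vs LFD). The clock shifts that passed were 5.01 h and 4.0 h for Long minus Equal light in LFD and HFD, -3.24 h and -4.17 h for Short minus Equal light, and -0.97 h for HFD minus LFD in Short light.

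The clock genes of 9 libraries read a time over 4 h from their label, and 8 of the 9 lie among the 16 libraries numbered 49 to 64 (two-sided Fisher's exact p 1.06e-07). RNA of muscle or pancreas was argued against, since 1 of the 9 was rich in those markers, and so was low depth, since their median depth was 25.5 M reads against quartiles of 21.14 M and 26.9 M in the others. A candidate explanation is that labels were exchanged between numbers 49 to 56 and 57 to 64, the pair that ranked 1 among all pairs of blocks of 8 compared. In the pairs 49/57, 53/61, 54/62 and 56/64, 8 of 8 libraries lay nearer to the partner's group over rhythmic genes outside the clock, and 6 of the 9 libraries whose diet genes sit on the other diet's side lie in these blocks (Fisher's exact p 0.000126). An exchange of the whole blocks is contradicted by pair 55/63. In squared distance, library 55 lay 7.22 from the partner's group and 1.08 from its own. Rhythmic genes leave 50/58, 51/59 and 52/60 open, where 1 of 6 libraries lay clearly nearer to the partner. In pair 50/58, of unlike diets, the diet genes of both libraries sat on the partner's side. Their diet scores, positive toward HFD, were 0.05 for LFD library 50 and -0.26 for HFD library 58. Both are among the 6 counted above, and they go with an exchange of this pair. Library 53 is also among the 6, with a diet score of -0.3. It is HFD Equal light ZT4 replicate 3, whose Fabp5 level of 8.20 stood apart from its group. Without numbers 49 to 64 the diet count rose from 3676 to 4015, while leaving out any other run of 16 tested gave 2629 to 3408. The exchange stays a hypothesis found and tested on the same data, no label was changed, and no biological explanation was tested.

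Rhythm differences between photoperiods covered many genes. RNA of muscle or pancreas and exchanged labels were argued against, because 95.9% of the 7612 genes of Long vs Short light kept the call with marker covariates, 6277 did without the 24 libraries rich in these markers, and 97.3% kept it without library numbers 49 to 64. The differences may reflect a single common shift in time per arm, since moving each arm by its clock shift left 0 genes past the threshold in limma and 0 in limma-voom (1641 and 1616 at an unadjusted p under 0.05), while 20 moves by shuffled shifts left a median of 3940.5 and a lowest count of 0 (medians of 479 for Long vs Equal and 1160 for Short vs Equal light, lowest 0 in both). Small differences beyond a shift are not excluded. The counts of 1641 and 1616 exceed the share of 0.05 that chance gives for independent genes. Of simulated rhythms of amplitude 0.6 added to LFD Long light alone, 44% were found by this test, which averages both diets. Whether a common shift is biological, set by photoperiod, or comes from a different event called ZT0 in each photoperiod cannot be told apart, because the labels hold 0 mentions of light hours.

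Of 12 pancreas acinar markers 11 were lower in HFD by limma, and Pnlip, Cpa1, Cel and Cela2a among them lost the call without replicate 1 (adjusted p from 0.177 to 0.233) and without replicate 3 (from 0.0807 to 0.125). Exchanged labels were argued against, because only 1 of the 12 pancreas-rich libraries lies in numbers 49 to 64, and 6 markers were called lower without those 16 libraries, exactly the bound set beforehand. Carry-over of pancreas tissue into single libraries stays open, because its tests used libraries picked by these same markers, so that at least 11 of 12 markers above log2 CPM 2 in 12 of the 12 pancreas-rich libraries (and in 3 of the others) decides nothing. Without the libraries rich in muscle or pancreas markers 0 markers were called lower in limma (4 at an unadjusted p under 0.05) and Cela1 was called higher (log2 difference 0.39, adjusted p 0.00121), and that is the outcome set beforehand for carry-over, but leaving out libraries by the marker itself shrinks the difference by construction, so that test decides nothing either. A diet effect was not tested apart from this and stays open, limma-voom called 0 of 12 lower over all libraries with a larger log2 difference for Pnlip (-2.69 against -1.96, adjusted p 0.156), and pancreas-rich libraries were 3 of 61 in HFD and 9 of 62 in LFD (two-sided Fisher's exact p 0.126).

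For each count, 100 splits of the libraries were compared, the real one included. Diet labels were shuffled within photoperiod and time, photoperiods within diet and time, and times within arm. The diet count of 3676 was reached in 1 split (highest other 1), that of Long light, 699, in 1 (14) and that of Short light, 990, in 1 (1). Only the real split reached these counts, which argues against chance. A share of 1 in 100 is the smallest that these splits can give, and it was not adjusted over the counts compared. The Equal light count of 986 was reached in 2 splits, a share under 0.05 that was not adjusted over the counts compared. The other split gave 1977 genes, more than the real one, so chance is not excluded there. The 4 genes of Long vs Equal light were reached in 2 splits (highest other 130), also a share under 0.05 without adjustment over the counts. The 1 gene of Short vs Equal light was reached in 7 (highest other 255). Chance cannot be excluded for either count. Other splits with many times the real count may come from a structure of the samples or from genes that vary together, which was not tested. Counts of 0 were reached in all 100 splits, with highest others of 16 for Long vs Short light, 38 within LFD, 11 within HFD, 93 for the diet by photoperiod interaction of level and 1 for that of rhythm.

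The counts of rhythmic genes were reached in 1 split each, with highest others of 167 for 3012 genes (LFD Equal light), 25 for 3395 (LFD Long light), 52 for 3906 (LFD Short light), 1509 for 2372 (HFD Equal light), 1 for 3137 (HFD Long light) and 201 for 2034 (HFD Short light). The rhythm differences were reached in 1 split each between photoperiods, with highest others of 1 for 7612 genes (Long vs Short light), 3 for 3421 (Long vs Equal) and 245 for 2349 (Short vs Equal). Only the real split reached these counts, which argues against chance for them, within the same limit on the smallest share. The 1 gene whose rhythm differed between diets was reached in 3 splits (highest other 6), a share under 0.05 that was not adjusted over the counts compared. Chance is not excluded for this count, and the gene also lost its call under several settings.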

How the results depend on the processing

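Fits with marker covariates, a pseudocount of 1 or limma-voom for levels, and those without marker-rich, widest, deviating-clock or numbered libraries, were chosen after seeing the data, and the other tests here were planned. Of 304 values of counts, list tests and shifts under settings other than left-out replicates, 275 kept their direction and side of the threshold, or stayed within 1.5 times for counts. For named genes, with left-out replicates included, 2020 of 2117 values did, 94 lost the call (30 genes) and 3 moved (Hlf). Limma-voom kept 3588 of the 3676 diet genes. The cause of the changes below was not tested. No paired analysis was possible because replicate numbers follow the order of deposit and pair nothing. The planned count test, the edgeR quasi-likelihood F test, was not run. Limma-trend was its fallback, and limma-voom on the recovered reads was the closest alternative. Depth limits genes near the floor most, as 1 read is worth 0.0422 CPM.

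Short vs Equal light gave 7 genes with library number as covariate, 2 with the mesor contrast, and by limma 0 without marker-rich libraries (1268 at unadjusted p), without deviating clocks (2006) and without numbers 49 to 64 (1731). Long vs Equal light gave 1 gene with marker covariates, 2 without marker-rich libraries, 0 without the 2 widest (1552 at unadjusted p) and 1 without numbers 49 to 64. With 24 and 12 h cosines 1563 genes were rhythmic in HFD Equal light and 2001 in HFD Long light, and with time as a factor 1696 in HFD Long light. The rhythm difference between diets gave 0 genes with 24 and 12 h cosines (327 at unadjusted p), with time as a factor (340) and without marker-rich libraries (394). That last setting removes 24 libraries, leaves 1 in the smallest group, which is assumed to vary like the others, and gave 189 diet genes in Long light, 1303 and 1874 rhythmic genes in LFD Equal and Long light and 1331 rhythm differences for Short vs Equal light. The diet by photoperiod term of rhythm gave 1 gene without the 2 widest libraries and 3 without deviating clocks, where Short vs Equal light gave 3682, a setting chosen by the rhythm itself. The clock shift of HFD minus LFD was -0.85 h in Short light as a median over genes (adjusted p 0.0553) and -1.23 h in Long light without numbers 49 to 64 (0.0432). Of 11 lists called between diets, 1 held with an estimated correlation, fry called all 11 and 2 more, and fry in either direction called 2. Of 6 between Long and Short light, 1 held with an estimated correlation, fry called 1 and fry in either direction 0.

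With each replicate number left out in turn, diet counts ranged over 2282 to 3269 (all photoperiods), 194 to 763 (Equal light), 172 to 606 (Long) and 120 to 626 (Short). Level counts of limma were 0 to 25 for Long vs Equal light, 0 to 2 for Short vs Equal, 0 to 1 for Long vs Short in LFD, and 0 for Long vs Short with both diets or in HFD and for the interaction. Rhythmic genes ranged over 1051 to 3175, 1782 to 2991 and 1611 to 3798 in LFD Equal, Long and Short light and over 940 to 2246, 1114 to 2532 and 835 to 1628 in HFD. Rhythm differences ranged over 5920 to 7187 (Long vs Short), 1376 to 3181 (Long vs Equal), 818 to 2463 (Short vs Equal), 0 to 1 (diet) and 0 (diet by photoperiod). Clock shifts ranged over 4.56 to 5.31 h and 3.28 to 4.26 h for Long minus Equal light in LFD and HFD, -3.78 to -2.82 h and -4.69 to -3.93 h for Short minus Equal light, and for HFD minus LFD over -0.45 to 0.61 h in Equal light, reversed to 0.61 h without replicate 3, -1.23 to -0.81 h in Long light and -1.13 to -0.7 h in Short light.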

Other observations

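The gene lists were tested as planned, and the comparison of shifts over other genes was chosen after the rhythm differences were seen. In HFD, acute phase genes went both ways, 6 up and 5 down of 16 (9 and 5 adjusted over the list alone): Orm3 rose by 1.20 on the log2 scale from a low level, Lcn2 by 1.06 and Hp by 0.43, while Fga, a fibrinogen chain gene, stood at -0.17 (camera adjusted p 0.206). Bile acid genes did too, 6 up and 2 down of 16 (6 and 2 adjusted over the list alone), with Cyp8b1, which sets the share of cholic acid, at 0.45 (adjusted p 1.13e-06), the transporter Slco1b2 at 0.16 and Baat at 0.15, against Slc10a1, which takes up bile salts from blood, at -0.24 (camera adjusted p 0.233). Slc10a1 and Baat lost their calls without replicate 1 (adjusted p 0.12 and 0.0825). Of 19 gluconeogenesis and fasting genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with the fasting regulator Creb3l3 at 0.23 and Gpt at 0.21 against the coactivator Ppargc1a at -0.33 (camera adjusted p 0.563, median -0.004, mean 0.048). Of 15 glycolysis genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), with Ldha at 0.20 against Pfkfb3 at -0.48, Pklr at -0.37 and Gpi1 at -0.33 (camera adjusted p 0.156), and without replicate 1 Pklr and Gpi1 had adjusted p-values of 0.234 and 0.0643. The cold-inducible RNA binding gene Rbm3 stood at -0.26 (adjusted p 1.45e-09), 1 of 2 called among 14 heat shock and temperature genes (1 up, 1 down, 0 and 1 over the list alone, camera adjusted p 0.152). Among female-biased liver genes 3 rose and 2 fell of 10 (3 and 2 adjusted over the list alone, camera adjusted p 0.159, fry 0.0433), with Cyp2b9 at 3.49 against Cyp2c69 at -1.15, and among male-biased genes 2 of 14 fell (2 over the list alone, 0.166), C6 at -0.24 and Cyp4a12b at -0.27, the latter with an adjusted p of 0.63 without replicate 1.

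Few clock genes differed in average level between diets. Of 19 clock and clock output genes 1 fell (1 adjusted over the list alone), Rora at -0.18 (adjusted p 0.00786, 0.0593 without replicate 1 and 0.0549 without replicate 2), with a camera adjusted p of 0.699. Of 14 periportal genes 2 fell, Sdhd at -0.11 and the urea cycle gene Cps1 at -0.16 (2 over the list alone, camera adjusted p 0.563, and Cps1 0.113 without replicate 1 and 0.0564 without replicate 2). Respiratory chain genes fell in 3 of 16 cases (3 over the list alone, 0.685, median 0.003, mean -0.011), with Ndufb8 at -0.12, Atp5o and Cox7a2, which all lost their calls without replicate 1 (adjusted p 0.292, 0.383 and 0.123), while 4 of 7 genes of the mitochondrial genome rose (4 over the list alone, 0.156). Blood genes gave 1 up and 3 down of 6 (1 and 3 over the list alone, 0.24), with Alas2 at 0.17 against Slc4a1 at -0.48, which had adjusted p-values of 0.0566 without replicate 1 and 0.13 without replicate 2. The unfolded protein response gave 2 up and 2 down of 19 (0 and 1 over the list alone, 0.267), the cell cycle 1 down of 18 (0 over the list alone, 0.233), lymphocytes 1 up of 11 (0 over the list alone, 0.48), endothelial cells 2 up of 13 (2 over the list alone, 0.138) and adipocytes 1 up of 7 (1 over the list alone, 0.219, and 0.019 by fry). In limma and in limma-voom, neutrophils (4 genes), cholangiocytes (6) and skeletal muscle (14) gave 0 called members between diets (0, 2 and 0 at an unadjusted p under 0.05 in limma), with camera adjusted p-values of 0.422 for the first pair of lists and a camera p of 0.903 for muscle.

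Genes outside the clock set that were rhythmic in both arms shifted by a median of 4.4 h from Equal to Long light in LFD and in HFD, and by -3.09 h and -3.54 h from Equal to Short light. Between diets their median shift was -0.48 h in Equal light (1199 genes), -0.57 h in Long light (1988) and -1.15 h in Short light (1456). No test was run on these medians, and genes are not independent replicates.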
